A study of Zea mays with 6 samples.

How the data were processed

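Gene expression was measured by RNA sequencing of total RNA from immature maize anthers with meiocytes in the first meiotic division, in 3 mop1 mutant libraries and 3 libraries of wild-type (WT) siblings, all in a Mo17/B73 hybrid background. Per the labels' protocols, RNA was extracted with a column kit for plant tissue and sequenced as paired-end Illumina reads by a service provider. The labels do not say whether the replicates were separate plants, or name a library kit, so p-values measure only the spread between these samples, which may be technical.

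The authors deposited 1 table of gene-level signal, named normalized counts in the labels, with 1 column per library and 39756 maize gene IDs in rows. Per the submitters' processing notes, Trimmomatic 0.39, HISAT2, SAMtools, HTSeq and DESeq2 were used. The role and order of these tools, other versions, the genome build, the annotation and the strand setting are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies may therefore have been split or dropped in ways that cannot be seen in the table. Because Mo17 reads can map less well than B73 reads to a single reference, a difference of haplotype between libraries could also appear as a difference in these values.

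The deposited values are read counts divided by 1 factor per library. In every column, 100% of the values were whole multiples of the column's smallest value, within a tolerance of 0.01 of a read, and whole reads were recovered by that division. The recovered reads came to between 22635163 and 26531475 per library, which is the depth behind all values. Size factors estimated again from the recovered reads with DESeq2 differed from the deposited scaling by -3.58% to 3.33%, relative to the mean of the libraries. Every column mapped to 1 sample through the column name in its label.

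The gene IDs carry no names in the table, and 0 of the 39756 IDs matched an ID, symbol or synonym in the table of 49888 reference genes used here (assembly Zm-B73-REFERENCE-NAM-5.0). The transcript of mop1 itself, the 16 gene lists fixed before the data were examined (small RNA machinery, DNA methylation, meiotic recombination, tapetum and anther wall, pollen, green tissue, flavonoids, heat shock, histones, replication, defense, jasmonate, ribosomal proteins, transposon-derived proteins, auxin and detoxification) and the position of genes relative to mop1 were therefore not analysed here. The same holds for the planned set tests and for the planned rule for naming genes, which required a symbol or description. In its place, the 2 genes with the largest fold in each direction among those past the threshold are given by ID. This choice was made after the values were seen.

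The main test was limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a trended and robust empirical Bayes step, two-sided, and Benjamini-Hochberg adjustment at 0.05. Genes were tested where the deposited value was at least 10 in at least 3 of the 6 libraries, which left 23150 genes. Of the other genes, 7185 were at 0 in all libraries. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The intervals given for fold changes are 95% intervals from the same fit. Intervals and limits made from reads cover counting error only. For a group with no reads, the limit was set at 3 reads over the group.

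Alternatives fixed before the data were examined were other pseudocounts, no filter and a stricter filter, TMM and quantile scaling, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) on the recovered reads, library weights, an empirical Bayes step without trend, a replicate block, other thresholds, and leaving out each library in turn. Blocked edgeR and DESeq2 fits, and further fits without libraries numbered 3, were added after seeing the data. The main fit had no block. The labels number the replicates 1 to 3 in both groups and state no pairing. Within each group the numbers follow the alphabetical order of the column names, which gives no pairing. The deviations of same-numbered libraries from their group means had correlations across genes of 0.15, 0.25 and 0.49. The numbers were treated as pairs in the blocked fits and when the splits were read. This pairing rests on the same data alone. Deviations from a mean of 3 libraries balance out, so correlations of both signs arise without any pairing. In addition, mop1 replicate 1 correlated more with WT replicate 2 (0.33) than with WT replicate 1.

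The 3 tools were tested on simulated data with the means, library sizes and dispersions of these 6 libraries and 23150 genes. In these data 200 genes were changed, drawn from those with a mean of at least 50. Each gene was drawn independently around 1 mean, so the simulation held no outlying library such as mop1 replicate 3. limma recovered 3 of 50 genes changed 2-fold, 35 of 50 changed 4-fold, 48 of 50 changed 8-fold and 47 of 50 changed 16-fold, and 10 of its 143 calls were unchanged genes. edgeR recovered 2, 35, 48 and 46 of 50, with 10 unchanged genes among 141 calls. DESeq2 recovered 13, 48, 49 and 50 of 50, with 88 unchanged genes among 248 calls. With no gene changed, limma and edgeR called 0 genes and DESeq2 called 42.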

Results

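RNA was profiled from immature anthers of maize carrying meiocytes in meiosis I. The mutants were homozygous for mop1 in a Mo17/B73 hybrid background, and the controls were homozygous wild-type siblings (WT). The gene mop1 encodes an RNA-dependent RNA polymerase of the RNA-directed DNA methylation pathway, in which small RNAs direct methylation to transposons near genes. There were 3 libraries per genotype. The recovered reads assigned to genes were 23392109, 23417208 and 26531475 in mop1 replicates 1 to 3, and 24969152, 22635163 and 24362801 in WT replicates 1 to 3. Between 28426 and 29286 genes had a value above 0 in a library. The 10 most abundant genes took 1.56% to 2.02% of the normalized total in the mop1 libraries and 2.29% to 2.87% in the WT libraries.

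Correlations within a genotype overlapped those between genotypes. Pearson correlations across the 23150 tested genes, on the log2 scale, ranged from 0.86 to 0.97 within a genotype and from 0.85 to 0.96 between genotypes. Genes are not independent replicates, so these values describe the libraries only. The WT libraries resembled one another, with correlations of 0.95 to 0.97. Among the mop1 libraries, replicates 1 and 2 correlated at 0.96, and replicate 3 correlated with them at 0.86 and 0.89. Its highest correlation, 0.91, was with WT replicate 3. No libraries agreed within sampling noise, the smallest chi-square per gene between any pair being 33.6.

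**Figure D1:**
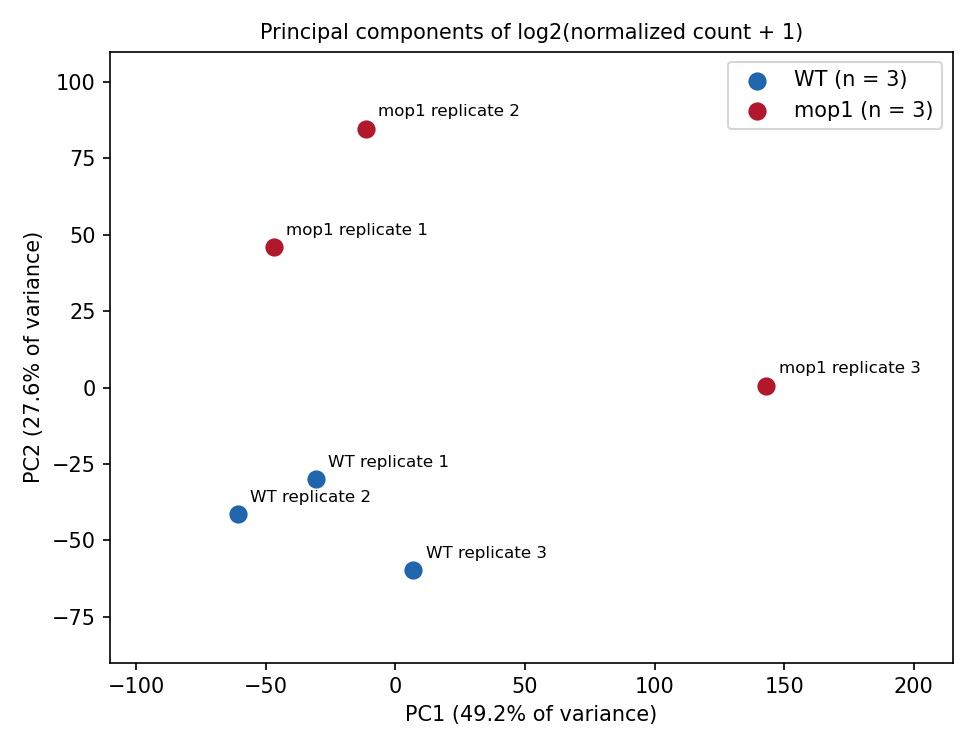
Principal components of log2(normalized count + 1) over 23150 tested genes, with 1 point per library (red, mop1; blue, WT) and the share of variance on each axis. The first component, 49.2% of the variance, sets mop1 replicate 3 apart from the other libraries. The second, 27.6%, places every mop1 library above the WT libraries. On it, mop1 replicates 1, 2 and 3 lie at 45.9, 84.6 and 0.66, and WT replicates 1, 2 and 3 at -30.1, -41.4 and -59.7.

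In mop1 replicate 3, 540 tested genes lay more than 4-fold below every other library and 10 lay more than 4-fold above. The other libraries had 3 to 56 such genes below and 1 to 69 above. The 540 genes had a median normalized count of 2.91 in mop1 replicate 3. Their medians in the other libraries ranged from 99.2 in WT replicate 3 to 249 in WT replicate 2. The median in mop1 replicate 2 was close to that in WT replicate 3. In mop1 replicate 3, 151 of them had no read. After quantile normalization, 328 genes lay more than 4-fold below every other library.

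The main comparison asked which transcripts differed between mop1 and WT anthers during meiosis I, the stage at which crossovers are formed. Of 23150 genes, 5 passed limma's test at an adjusted p of 0.05, with 2 higher and 3 lower in mop1. A pair of genes was expressed in WT and almost or wholly without reads in every mop1 library, and 1 gene was near background in WT and strongly expressed in every mop1 library. These 5 calls stand beside the separation of mop1 replicate 3 described above, and without that library 208 genes passed, 166 higher and 42 lower, all 5 among them. Leaving out mop1 replicate 1 gave 50 genes, 3 higher and 47 lower, and leaving out mop1 replicate 2 gave 1. Leaving out WT replicate 1, 2 or 3 gave 0 genes by limma, with 1600, 1379 and 1622 genes at an unadjusted p under 0.05.

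The gene Zm00001eb072130 rose from 5.69 ± 1.27 normalized counts in WT to 395 ± 52.1 in mop1 (SD, n = 3 each). Its log2 fold change was 5.90 with a standard error of 0.30 and an adjusted p of 0.0063 by limma, and over the alternatives the adjusted p reached 0.071, with 4 of 22 ending the call. The gene Zm00001eb432880 rose from 182 ± 32.9 to 1112 ± 191 (SD, n = 3 each), a log2 fold change of 2.60 with a standard error of 0.21 and an adjusted p of 0.034 by limma. Over the alternatives its adjusted p reached 0.25, with 7 of 22 ending the call.

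The gene Zm00001eb080660 had no read in any mop1 library and 238 ± 111 normalized counts in WT (SD, n = 3), where 863 reads were recovered. Against a limit of 3 reads over the mop1 group, it was at least 313-fold lower in mop1, and limma gave an adjusted p of 0.0074. edgeR did not call it on the recovered reads, with an adjusted p of 0.12, and over all alternatives its adjusted p ranged from 9.0e-14 to 0.26. The gene Zm00001eb018590 had 2 reads over the mop1 libraries and 939 over the WT libraries. Its mean fell from 256 ± 26.7 to 0.50 ± 0.43 normalized counts (SD, n = 3 each), a ratio of 510 with a 95% counting interval of 141 to 4219 and an adjusted p of 0.0063 by limma. Over the alternatives its adjusted p reached 0.15, with 5 of 22 ending the call.

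The remaining gene past the threshold fell from 1050 ± 120 normalized counts in WT to 282 ± 24.6 in mop1 (SD, n = 3 each), with an adjusted p of 0.038 by limma. It was lower in 3 of 3 mop1 libraries than in any WT library. With the replicate number as a block its adjusted p was 0.083, and over all alternatives it ranged from 1.2e-17 to 0.32, 10 of the 22 ending the call. With the block in limma, the other 4 genes had adjusted p values of 0.036 to 0.037. With the block in edgeR, Zm00001eb072130 passed at 0.043, and Zm00001eb432880 at 0.093, Zm00001eb018590 at 0.090 and Zm00001eb080660 at 0.26 did not. This remaining gene and Zm00001eb080660 lay within the same 200 consecutive tested genes in ID order, which held 10 of the 100 genes with the lowest p. Genomic positions and annotations of these genes are not used here, since their IDs were not matched to names or coordinates.

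**Figure D2:**
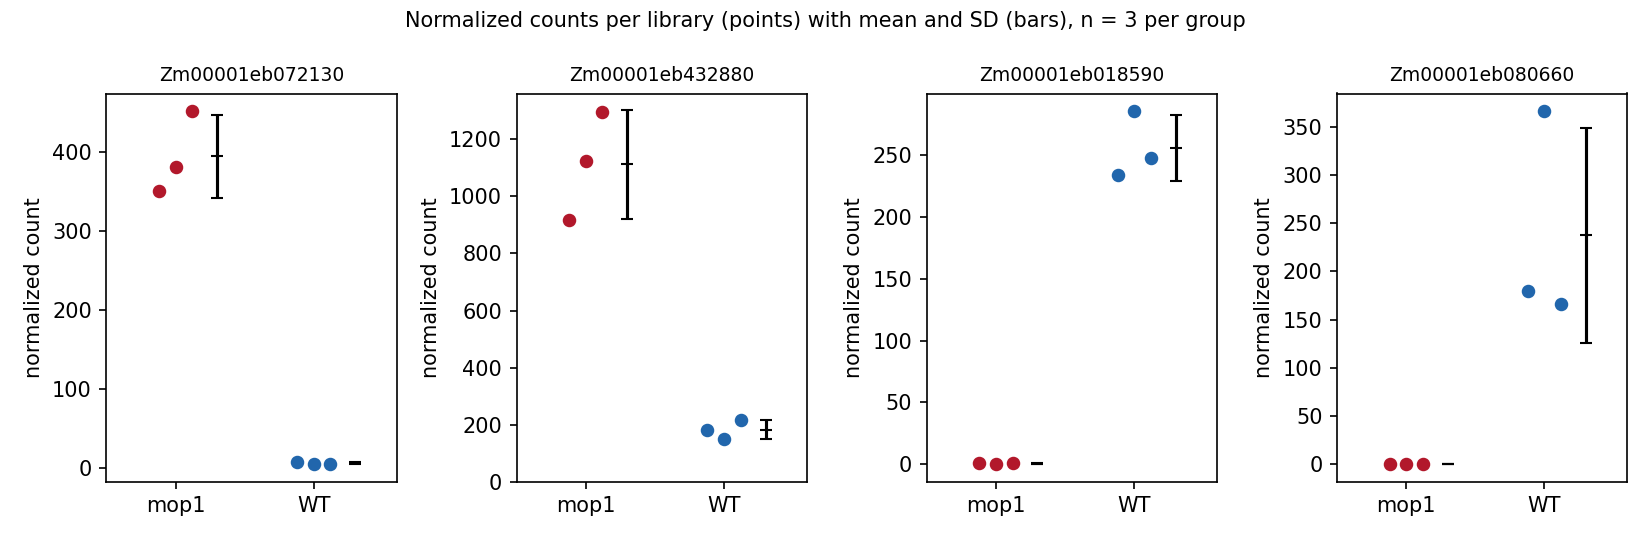
Normalized counts of 4 genes past the threshold, with 1 point per library, and the mean and SD of 3 libraries as bars beside the points (red, mop1; blue, WT; linear axes). The first 2 panels show genes higher in every mop1 library than in any WT library, and the last 2 show genes at 0 or 1 read in each mop1 library.

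Count models gave other totals on the same recovered reads. edgeR's quasi-likelihood test called 3 genes, 2 higher and 1 lower in mop1, and all 3 were among the 5 genes called by limma. DESeq2 called 445 genes, 220 higher and 225 lower, including all 5. In simulated data DESeq2 gave 88 unchanged genes among 248 calls. On the real data, a split of the libraries that placed WT replicate 2 with mop1 replicates 1 and 2 gave 443 genes by DESeq2. That split leaves the libraries numbered 2 together and those numbered 3 together. The other splits that part all 3 numbered pairs gave 3 to 20 genes by DESeq2. The pairing was read from the same data, so it does not set the split with 443 genes aside. With WT replicate 1 in the place of mop1 replicate 3, DESeq2 called 352 genes, and with mop1 replicate 1 grouped with WT replicates 1 and 2 it called 129.

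Below the adjusted threshold, 2406 genes had an unadjusted p under 0.05 by limma, against 1158 given by chance, with 959 higher and 1447 lower in mop1. The number was 4639 without mop1 replicate 3 (2057 higher, 2582 lower), 1528 without mop1 replicate 2 and 2603 without mop1 replicate 1. After quantile normalization the corresponding numbers were 1222 higher and 1196 lower, so the excess of lower genes depended on the scaling. Among genes with a mean of 1000 or more, 192 were higher and 482 lower, and after quantile normalization 266 and 380. Groups did not overlap at 4104 genes, or 17.7% of those tested, where chance gives 10%. One other split of the libraries gave more genes with an unadjusted p under 0.05 than the real one, 2709 against 2406.

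**Figure D3:**
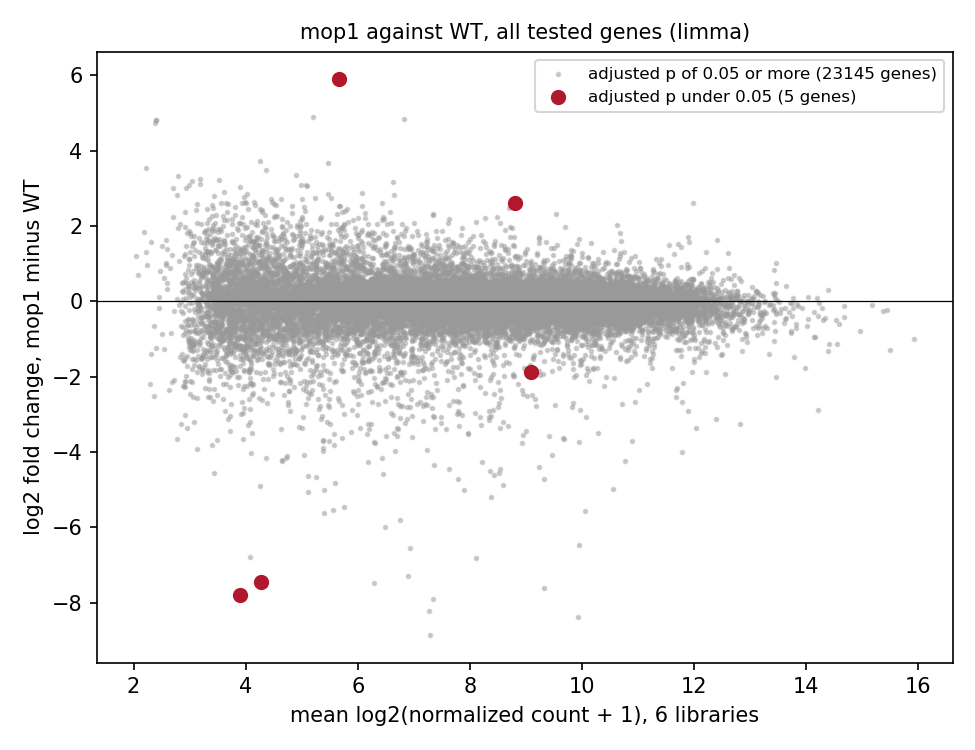
Log2 fold change of mop1 over WT (vertical axis) against the mean log2(normalized count + 1) of 6 libraries (horizontal axis), with 1 point per tested gene and genes past limma's threshold in red. The 5 red genes lie at log2 fold changes from -7.80 to 5.90, and other genes of similar fold, in grey, did not pass.

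For part of the transcriptome, the interval of a gene taken singly lay within narrow limits. These intervals are not adjusted for the number of genes. They also take the label of mop1 replicate 3 as right, which is not settled. The 95% interval of the fold change lay within 2-fold in either direction for 12695 genes (54.8%) and within 4-fold for 19601 genes (84.7%). Among genes with a mean under 50, the interval lay within 2-fold for 4.22%, against 74.1% of genes with a mean of 1000 or more. The median standard error of the log2 fold change was 0.27. A fold change of at least 2 in either direction was estimated for 2151 genes, and 5 of these passed the threshold. Why the others did not pass was not tested. In simulated data with the same dispersions, but no outlying library, limma recovered 3 of 50 genes changed 2-fold and 35 of 50 changed 4-fold. The changed genes had a mean of at least 50, so recovery at lower genes is not known. Changes of 2-fold were mostly not detectable in that setting.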

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

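The count of 5 genes (2 higher, 3 lower) stayed within 1.5 times under pseudocount 0.5, TMM scaling (4) and quantile normalization (6). Requiring a log2 fold change of at least 1 in the main fit also left 5. That was certain, since the smallest of the called folds was -1.89. The replicate block gave 5 genes, 3 higher and 2 lower, and 4 of these were among the original 5. The count moved to 8 with pseudocount 5 (5 lower), to 10 with no filter (5 higher, 5 lower) and to 1 at a mean of at least 50 (1 higher, 0 lower, where the other 3 genes given by ID had adjusted p values of 0.055 to 0.096). It moved to 18 with library weights (10 higher, 8 lower), to 9 without trend or robust steps (6 higher), and to 11 at an adjusted p of 0.1 (4 higher, 7 lower). edgeR called 3 (1 lower) and DESeq2 445 (220 higher, 225 lower). With a replicate block, edgeR called 2 (0 lower, with 1 of the original 5) and DESeq2 985 (408 higher, 577 lower). Leaving out 1 library gave 0 to 208 genes, with 0 to 166 higher and 0 to 47 lower. The counts were 50 without mop1 replicate 1, 1 without mop1 replicate 2, 208 without mop1 replicate 3 and 0 by limma without each WT library, where 1379 to 1622 genes had an unadjusted p under 0.05. Without both libraries numbered 3 the count was 141 (127 higher, 14 lower). Without mop1 replicate 3, DESeq2 called 1988 (1250 higher, 738 lower) and edgeR 279 (240 higher, 39 lower). The blocked count models and these 3 fits were chosen after seeing the data. Fewer libraries and genes tested enter some of these fits; beyond that the cause was not tested. The 4 genes given by ID kept their direction under all 22 alternatives, and the number in which each passed was 15 to 18. Alternatives for mop1, the gene lists and the distance from mop1 were not run, because gene IDs were not matched to names. Low genes were estimated less exactly: the median standard error was 0.55 at a mean under 50 and 0.21 at a mean of 1000 or more. Whether depth or spread between samples caused this was not tested.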

Other observations

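The tests of depth, scaling, ID order, splits under limma, shared reads and the chromosome segment were chosen after their results had been seen at least in part, and so were all but the first of the tests of the label of mop1 replicate 3. The window of IDs, the number of genes and the limits of the run in WT replicate 2 were set after several others had been looked at.

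A small set of genes was present in 1 genotype only, taken as at least 10 normalized counts in every library of one group and at most 1 read in every library of the other. There were 3 such genes in mop1, each with no read in WT, and 2 in WT. The 3 genes of mop1 had means of 27.5 ± 6.30, 29.9 ± 18.2 and 27.5 ± 6.39 normalized counts (SD, n = 3), and adjusted p values by limma of 0.10, 0.26 and 0.10, so none passed the threshold. The 2 genes of WT are those given above, at 238 and 256 normalized counts. Other splits of the libraries gave 0 to 4 such genes, against 5 for the real one.

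The 6 libraries can be parted in 10 ways into 3 and 3, too few for a share under 0.05. By limma the real split gave 5 genes and the highest other split 1, by edgeR 3 and 1, and by DESeq2 445 and 443. In each case 1 split, the real one, gave as many. Among the 4 splits that part all 3 numbered pairs, the blocked limma fit gave 5 genes for the real split and 0 for the highest other. Without the block, DESeq2 gave 445 genes for the real split of these 4 and 20, 9 and 3 for the others, and edgeR gave 3 and then 0 in each. The split with 443 genes by DESeq2 has WT replicate 2 in the place of mop1 replicate 3, and so keeps the libraries numbered 2 together in one group and those numbered 3 together in the other. These 4 splits are also too few for a share under 0.05. The pairing behind them was read from the same data, so they are not an independent check.

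The first pattern is mop1 replicate 3, with 540 genes more than 4-fold below every other library. Lower depth is argued against, since it had the most recovered reads, 26531475. Its median deviation over all tested genes was 0.0505 on the log2 scale. The deposited scaling, close to DESeq2's size factors, holds such a median near 0, so this value cannot decide on scaling. After quantile normalization the count was 328. At 832 to 1088 genes mop1 replicate 3 lay more than 4-fold below both WT libraries of a pair. The WT library left out of the pair had 27 to 172 such genes, mop1 replicate 1 had 63 to 104 and mop1 replicate 2 had 260 to 311. The 540 genes are below every such pair by definition. These counts therefore restate the pattern and are no separate test of a wrong label alone as its cause. They show only that mop1 replicate 3 had more such genes than any WT library did. Whether the label itself is right is a separate matter that cannot be told apart, because 3 tests of it, tried in turn, disagreed. A graded difference shared by WT replicate 3, such as anther stage, may contribute. It need not be particular to that library. By median normalized count at the 540 genes, mop1 replicate 2 lay nearly as low as WT replicate 3. There, mop1 replicate 1 and WT replicates 1 and 2 had higher medians. Only the deviation of WT replicate 3 was tested further. At the 540 genes, WT replicate 3 deviated from the mean of the other WT libraries by a median of -0.87 on the log2 scale. It lay below that mean at 86.5% of them, against 48.1% of all tested genes. The 95% interval of that median, from a bootstrap over genes, was -0.91 to -0.78. Genes are not independent replicates, so the interval does not measure spread between libraries. A biological cause tied to the genotype stays open as untested.

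The tests of that label gave these values. The test set down before its value was known met its criterion for a wrong label. At the 208 genes called without mop1 replicate 3, its median position was -0.0079 between WT at 0 and the other mop1 libraries at 1. There 38 genes were nearer mop1, and the 95% interval from a bootstrap over genes was -0.086 to 0.085. Those genes were chosen as parting mop1 replicates 1 and 2 from WT, which can draw a library left out toward WT. Neither of those replicates was held out in the same way, so the position of a rightly labelled mop1 library is not known. A test added after the first result was undecided, with mop1 replicate 3 on the mop1 side at 6 of 14 genes present in 1 group only. The last criterion, set after both and with its counts already seen, went against a wrong label. Among 16545 genes with at least 100 normalized counts in every WT library, 2 were absent from mop1 replicates 1 and 2, and both were among the 55 absent from mop1 replicate 3 (Fisher's exact test, two-sided, p = 1.09e-05). It rests on 2 genes, which are among the 5 called. With each WT library held out in turn, 0 genes at 100 or more in the remaining WT libraries were absent from it. No such overlap could therefore arise in a WT library. Genes gained in mop1 do not decide either. Of 10644 genes absent from every WT library, 12 were present in mop1 replicates 1 and 2 and 10 in mop1 replicate 3. With 3 of them shared, Fisher's exact test, two-sided, gave p = 1.3e-07. A held-out WT library was judged on genes absent from the remaining WT libraries only, a looser set. On such sets WT replicate 2 shared 5 of 34 (p = 8.9e-09 by the same exact test), WT replicate 1 shared 2 of 22 and WT replicate 3 shared 0 of 17. Because the sets differ, these p-values cannot be ranked against each other. WT replicates 1, 2 and 3 were also held out in turn, which gave 10, 76 and 141 called genes. The held-out library was nearer mop1 at 2, 8 and 2 of these, and mop1 replicate 3 at 5, 12 and 19. The median positions were 0.13, 0.20 and -0.23 for the held-out library and 0.47, -0.068 and -0.17 for mop1 replicate 3. With WT replicate 2 held out, mop1 replicate 3 was thus nearer WT by the median than the held-out library.

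The second pattern is the crowding of changed genes along the ID numbers. Of the 100 genes with the lowest p, 10 lay within 200 consecutive tested genes, 9 of them lower in mop1 and 2 of them among the 5 called genes, where the fullest window of shuffled orders held 4.66 on average. Chance order is argued against (permutation p = 0.0001, the smallest that 10000 shuffles can give). The log2 fold changes in the window ran from -7.80 to 1.47, with an SD of 2.81. This argues against 1 common fold from reads shared by all 10 genes. It cannot tell whether some of them are near-identical copies that share reads. The lowest fold is that of Zm00001eb080660, which had no read in mop1. Library structure that does not follow the genotype cannot be told apart, because 3 of 10 splits gave a window as full, the highest with 15 genes. The window of the real split began at rank 4412 in ID order, and the others as full began elsewhere, at ranks 20651 and 15184. The split with mop1 replicates 1 and 3 and WT replicate 2 in 1 group had its fullest window, of 5 genes, at rank 4428. Such splits, 10 in all, are too few to decide. If ID numbers follow position along chromosomes, which was not checked here, a haplotype linked to the mutation might give such a window, those 2 calls included, and stays open as untested. Over 19 alternatives the fullest window held 5 to 11 genes, with 5 when mop1 replicate 1 was left out. Whether it was the same window each time was not compared.

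The third pattern is a run of genes in WT replicate 2. There, 312 genes in 2 stretches of IDs exceeded every other library more than 2-fold, with up to 48 raised genes in 50 consecutive IDs, where the other libraries reached 5. The median rise was 4.89-fold and the SD of the log2 deviations 0.39. Near-identical copies that share reads might give so small an SD, although choosing genes by their rise narrows it. The raised genes were low, with a median of 6.46 normalized counts in the other libraries (quartiles 3.52 and 17.9), and 129 of the 312 passed the filter for testing. That they form a single family is not shown. A changed chromosome segment is argued against, since the 34 genes inside the run with a mean of at least 200 deviated by a median of -0.0076 on the log2 scale. The 312 raised genes took 0.108% of the normalized total in WT replicate 2 and 0.0187% to 0.0241% in the other libraries, and what they encode was not analysed here.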
